A study of Homo sapiens with 9 samples.

How the data were processed

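The 9 libraries hold RNA from streptavidin-bound ER polysomes of HEK293 cell lines that express LRRC59-BioID, SEC61B-BioID or neither (EV), with 3 libraries per line. Per the labels, doxycycline induction lasted 16 h at 10 ng/mL (5 ng/mL for SEC61B-BioID), biotin was given at 50 uM for 3 h, and cells were rinsed with cycloheximide at 50 ug/mL for 10 min. Per the labels' protocols, 0.03% digitonin released the cytosol, a rinse at 0.004% followed, and 1% NP-40 in high salt dissolved the membranes. Polysomes were taken from the void of a Sephacryl column and bound to streptavidin, and 10 ng of RNA entered each library, per the labels. The deposited values are whole-number counts of reads per gene symbol, with no normalization. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with HISAT2 to GRCh38 and counted with HTSeq 0.5.4p3. The HISAT2 version, annotation release, counting mode and strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart with certainty.

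Each deposited count file holds 44786 symbols and 5 counter lines for reads not assigned to a gene, which were kept out of library sizes and tests. Reads with more than 1 alignment were 70.1% to 79.0% of all reads in LRRC59-BioID, 59.5% to 69.5% in SEC61B-BioID and 41.5% to 60.4% in EV. Reads outside genes were 3.84% to 17.1%, ambiguous reads 1.89% to 4.52%, unaligned reads 1.85% to 5.07% and low-quality reads 0% of a library. Symbols were matched to GENCODE 29 by name (29314) or through RefSeq symbols (102) and older symbols (709). The 14661 left unmatched, apart from Metazoa_SRP, held 1.30% of the gene counts. Libraries of 1 group correlated with r between 0.974 and 0.984 on log CPM, and the lowest chi-square per degree of freedom between any pair within a group was 9.72, so no library was counted as a repeat of another.

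Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 17086, and TMM factors ran from 0.727 to 1.30. A robust quasi-likelihood model with the 3 groups was fitted to all 9 libraries, so that the groups share 1 estimate of spread, and 3 contrasts were taken, each reporter against EV and LRRC59-BioID against SEC61B-BioID. Adjusted p-values follow Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Shares of reads were compared with two-sided exact permutation tests, which do not use the replicate numbers.

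Before the data were examined, the groups, the test, the alternatives, the rule for naming genes and 31 gene lists were fixed. The lists cover ER-targeted proteins (translocation machinery, ER chaperones, N-glycosylation, secreted and matrix proteins, receptors, lysosome, Golgi glycosyltransferases, solute carriers, TMEM genes). Cholesterol synthesis, tail-anchored proteins and stress response targets were listed as well, though not all of their members are ER proteins. The lists also cover cytosolic proteins (ribosome, translation factors, glycolysis, cytoskeleton, proteasome, chaperones), nuclear ones (ZNF genes, splicing factors, histones), mitochondrial ones (mitochondrially encoded mRNAs, respiratory chain, mitochondrial ribosome), biotin carboxylases with biotin handling, nucleus-retained RNAs, 7SL RNA, hosts of small nucleolar RNAs, cell cycle, immediate early genes and markers of other cell types. The 30 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera asks whether a list stands apart from other genes. The same test with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, were the alternatives.

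For each contrast the text names LRRC59 and SEC61B, and the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those called, with at least 20 CPM in the higher group and no overlap between the 3 libraries of each group. For a described list it names up to 4 members with the smallest p, or any member of a list of 13 or fewer. EPRS in SEC61B-BioID and between the reporters, MARS between the reporters, the other genes of the multisynthetase complex, Metazoa_SRP and the 7SL pseudogenes, RMRP, RN7SK, RPPH1 and SCARNA2 lie outside that rule where it does not cover them and were chosen after their values were seen.

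Replicate numbers come from the labels, which do not say what a number shares. Deviations from the group means correlated between same-numbered libraries by 0.185, 0.160 and 0.150 for LRRC59-BioID with EV and by 0.354, 0.542 and 0.310 for SEC61B-BioID with EV. Each lay above the minimum of 0.1, so these numbers were treated as pairing the libraries. Blocked values therefore stand beside the results against EV that they change. The reporters' libraries did not all reach that minimum with each other (0.368, 0.0799 and −0.0347), so pairing by number is not settled. Blocked values of that comparison are given once, with the other alternatives.

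The gene test was checked on simulated counts with 200 changed genes among 17086 for each contrast. Of 50 genes changed 2-fold, 4-fold, 8-fold and 16-fold, it recovered 21, 48, 48 and 50 for LRRC59-BioID against EV, 28, 47, 49 and 48 for SEC61B-BioID against EV, and 29, 47, 50 and 49 between the reporters. Unchanged genes called numbered 9, 16 and 9. The list test called 10 of 10 lists of 40 genes raised 1.5-fold and 0 of 20 others in each contrast, with genes simulated as independent.

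Alternatives tried for the counts of genes, the reporter transcripts, the correlation and the lists were RLE size factors, library size alone, a filter at 1 CPM in 3 libraries, a fit of the 6 compared libraries, the replicate block, leaving out mitochondrial and non-coding genes and leaving out each library. No filter beyond 1 read and DESeq2 1.42.0 were tried for all of these except the lists, and a 2-fold minimum for the counts of genes. DESeq2 gave 0 missing adjusted p-values. Offsets for GC content and transcript length, as splines with 5 degrees of freedom, alone and with the block, were added after the data were seen. Correlations of both reporters' changes were set beside 20 simulations of unchanged groups that share 1 set of simulated EV libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.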

Results

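The series measured the RNA of endoplasmic reticulum (ER) polysomes that carried a biotin label, in stable inducible HEK293 cells, a human embryonic kidney line that another label of the same samples names as 293T. In BioID, a biotin ligase fused to a protein of interest tags proteins within its reach, and streptavidin then recovers what was tagged. One reporter was LRRC59, a ribosome-binding membrane protein of the ER, and the other was SEC61B, a subunit of the SEC61 channel through which new proteins enter the ER. The null line, named EV in the labels, supplied the background that streptavidin recovers without either reporter. Each of the 3 groups had 3 libraries, 9 in all. The series design calls them biological replicates but names no culture or day, so p-values measure the spread between these libraries. Cells with LRRC59-BioID and EV received 10 ng/mL doxycycline and cells with SEC61B-BioID 5 ng/mL, so dose and line cannot be separated wherever SEC61B-BioID is compared.

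Counts assigned to genes were 13357701, 13237636 and 11205264 in LRRC59-BioID replicates 1, 2 and 3. The SEC61B-BioID replicates had 18001437, 15400116 and 15805290, and the EV replicates 14526696, 16138187 and 16397340. At this depth 17086 of 44786 gene symbols could be tested. The common biological coefficient of variation was 0.190. Values per gene are CPM, counts scaled to a common library size with TMM factors, as mean ± SD over n = 3 libraries, and fold changes are log2 values with their standard error (SE) from edgeR's quasi-likelihood fit. Positions are those of GENCODE 29 on GRCh38.

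Each reporter's own transcript was highest in the libraries that carry its name. LRRC59 (chromosome 17, 50375059 to 50397553) stood at 2108.5 ± 495 CPM in LRRC59-BioID, at 151 ± 19.6 CPM in SEC61B-BioID and at 107 ± 12.9 CPM in EV. Its log2 fold change over EV was 4.30 (SE 0.27, edgeR adjusted p = 9.81e-08). SEC61B (chromosome 9, 99222064 to 99230615) stood at 214 ± 82.5 CPM in SEC61B-BioID, at 34.1 ± 4.45 CPM in LRRC59-BioID and at 21.5 ± 6.57 CPM in EV, a log2 fold change over EV of 3.32 (SE 0.28, edgeR adjusted p = 8.02e-06). In both cases all 3 libraries of the reporter lay above all 3 of EV. The counts do not separate the transgene from the endogenous gene.

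The RNA of the signal recognition particle, 7SL, which belongs to the particle that brings ribosomes with a signal peptide to the ER, took a higher share of counts in both reporter groups than in EV. All 7SL loci together took 31.7 ± 10.0% of the gene counts in LRRC59-BioID, 14.7 ± 3.01% in SEC61B-BioID and 0.344 ± 0.153% in EV (SD, n = 3 each). The mean shares were 91.9 and 42.6 times that of EV, with no overlap of libraries. A two-sided exact permutation test gave p = 0.1 for each reporter, which is the smallest p that 3 against 3 libraries allow. RN7SL1 (chromosome 14, 49586580 to 49586878) had a log2 fold change of 6.48 (SE 0.70, edgeR adjusted p = 2.10e-05) in LRRC59-BioID and 4.83 (SE 0.65, edgeR adjusted p = 0.000358) in SEC61B-BioID. It was the 1 member of the 7SL list with enough counts to test, and the files name further copies Metazoa_SRP, without a position. Of 65 tested 7SL pseudogenes, 55 were higher in LRRC59-BioID and 49 in SEC61B-BioID, but these near-identical copies share reads, so single loci are uncertain. Between the reporters RN7SL1 differed by a log2 value of 1.65 (SE 0.57), which did not pass (edgeR adjusted p = 0.695). The share of all loci in LRRC59-BioID was 2.16 times that in SEC61B-BioID with no overlap of libraries (two-sided exact permutation p = 0.1, the smallest possible). Of the pseudogenes, RN7SL836P, RN7SL575P and RN7SL660P were called higher in LRRC59-BioID than in SEC61B-BioID, by 1.85 (SE 0.30), 1.81 (SE 0.33) and 1.97 (SE 0.36), with edgeR adjusted p of 0.0200, 0.0417 and 0.0433. In the same order their edgeR adjusted p was 0.106, 0.205 and 0.237 without LRRC59-BioID replicate 1, 0.109, 0.195 and 0.205 without LRRC59-BioID replicate 3, 0.0877, 0.128 and 0.127 without SEC61B-BioID replicate 1 and 0.105, 0.163 and 0.215 without SEC61B-BioID replicate 2. Without SEC61B-BioID replicate 3 it was 0.0300, 0.111 and 0.124.

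**Figure D1:**
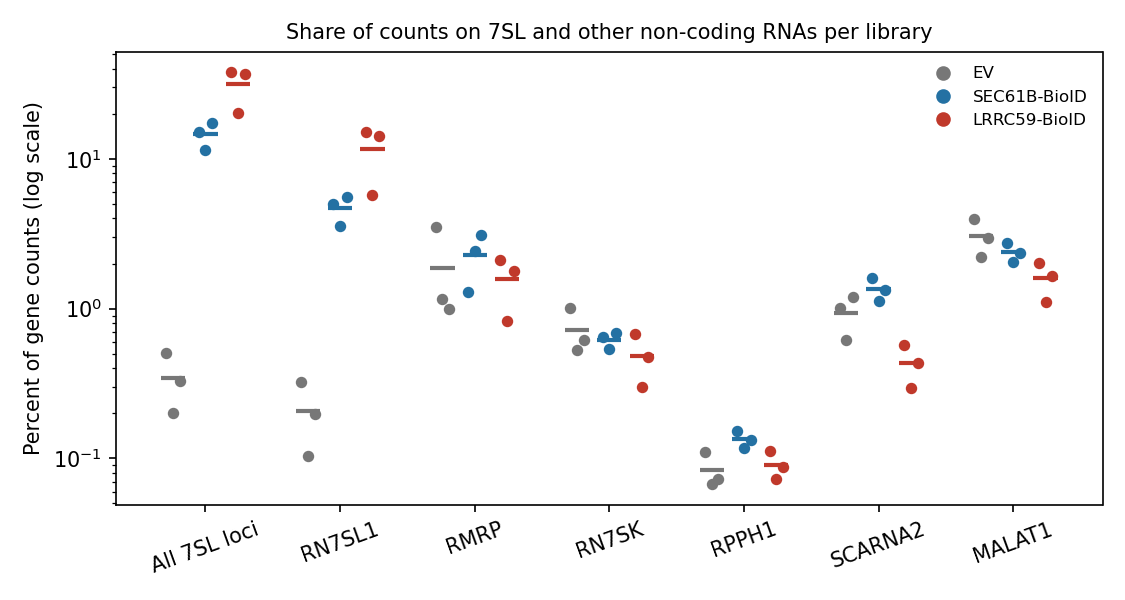
Percent of gene counts (log axis) on all 7SL loci and on 6 other RNAs in each library, with points for libraries and bars for the mean of 3. All 7SL loci take 31.7% of counts in LRRC59-BioID, 14.7% in SEC61B-BioID and 0.344% in EV on average.

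Reads outside single genes also differed by group. Reads with more than 1 alignment, which the counter leaves unassigned, made up 74.9 ± 4.48% of all reads in LRRC59-BioID, 63.6 ± 5.24% in SEC61B-BioID and 48.0 ± 10.7% in EV (two-sided exact permutation p = 0.1 and 0.2 against EV, smallest possible 0.1). By replicate number the share was 69.5%, 59.5% and 61.9% in SEC61B-BioID against 60.4%, 42.2% and 41.5% in EV. Reads outside annotated genes made up 4.87 ± 0.891%, 8.38 ± 1.58% and 15.0 ± 3.59% in the same order (exact permutation p = 0.1 for each against EV). Protein-coding genes held 60.9 ± 11.5%, 74.1 ± 3.16% and 87.4 ± 3.14% of the gene counts.

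The comparison of LRRC59-BioID with EV asks which mRNAs sat on polysomes near LRRC59 beyond the background of the null line. All 9 libraries are streptavidin-bound, with no total RNA beside them. Recovery near LRRC59 therefore cannot be told apart from a difference in expression between the lines. Messages for secreted, lysosomal, cell-surface and ER-resident proteins were higher with LRRC59-BioID, as were histone and mitochondrially encoded messages, while ZNF messages were lower. These are list calls at a preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.437). The histone and mitochondrially encoded lists did not pass with fry either (fry adjusted p = 0.0933 and 0.0817). edgeR called 1940 genes higher and 1293 lower at an adjusted p under 0.05, 620 and 434 of them by at least 2-fold. The libraries of the groups did not overlap for 36.7% of tested genes, where chance gives 10%.

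Among called protein-coding genes with at least 20 CPM in the higher group and no overlap of libraries, MAP7D2, a microtubule-associated protein (chromosome X, 20006713 to 20116917), had the largest rise, from 0.585 ± 0.122 CPM in EV to 25.3 ± 3.88 CPM (log2 fold change 5.40, SE 0.25, edgeR adjusted p = 2.10e-09). VCL, the adhesion protein vinculin, rose by 4.67 (SE 0.55, edgeR adjusted p = 0.000165). Among the top genes were 4 of the cytosolic multisynthetase complex, which charges tRNAs. MARS, its methionyl-tRNA synthetase, rose from 192 ± 10.6 to 4803 ± 4175 CPM (log2 fold change 4.65, SE 0.50), the scaffold AIMP1 by 4.31 (SE 0.51), the glutaminyl enzyme QARS by 3.35 (SE 0.41) and the dual enzyme EPRS by 2.24 (SE 0.44), with edgeR adjusted p of 2.88e-05, 0.000300, 8.23e-05 and 0.00661. LRRC59-BioID replicate 2 had the highest value of all 5 genes, and without it the log2 fold changes were 3.65 for MARS, 3.60 for AIMP1, 2.55 for QARS, 1.33 for EPRS and 3.62 for VCL, all still called. EPRS lost its call without EV replicate 2 (2.19, edgeR adjusted p = 0.0518). ASTN1, a neuronal membrane protein, rose by 2.94 (SE 0.19), the receptor NOTCH3 by 2.21 (SE 0.23) and the secreted protease HTRA1 by 2.08 (SE 0.25).

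**Figure D2:**
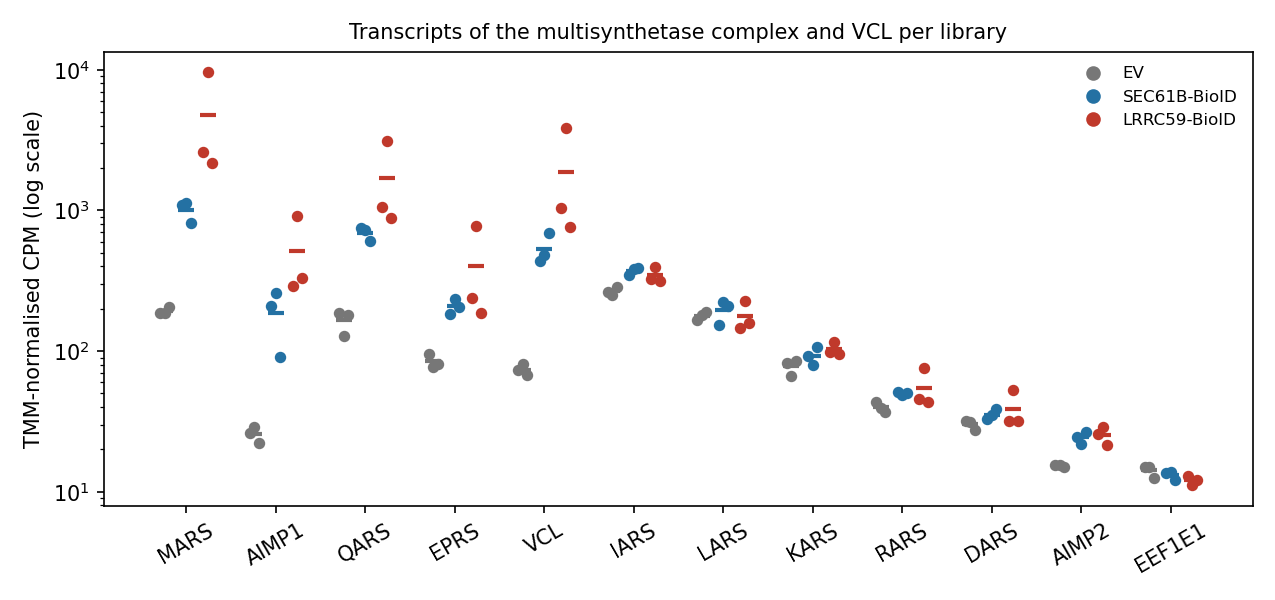
TMM-scaled CPM (log axis) per library of 4 multisynthetase genes and VCL, followed by 7 other genes of the complex, with points for libraries and bars for the mean of 3. MARS averages 192 CPM in EV and 4803 CPM in LRRC59-BioID, where replicate 2 is highest.

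Of the 30 gene lists tested, camera with its preset correlation of 0.01 called 23, of which 20 were higher and 3 lower. With an estimated correlation 0 lists passed (lowest adjusted p = 0.437), and fry called 11. Those 11 were the ER-targeted lists, stress response targets and ZNF genes (fry adjusted p from 0.0122 to 0.0255). Histone genes (fry adjusted p = 0.0933), mitochondrially encoded mRNAs (0.0817) and the other lists did not pass with fry. Of the 10 splits of the 6 libraries into 3 and 3, camera called as many lists or more in 4, the real split included. Scaling by library size alone moved the median of all tested genes to −0.65, and the medians of 15 of the 20 raised lists then fell below 0. The exceptions were the secreted, lysosomal, glycosylation, histone and mitochondrially encoded lists. Relative to the median of all genes, 0 of the 23 lists changed sign.

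Secreted and matrix proteins had a median log2 fold change of 0.86, with 41 of 59 tested members higher and 0 lower, or 45 and 1 adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). The basement membrane genes LAMA1 and HSPG2 rose by 1.94 (SE 0.22) and 1.45 (SE 0.23), fibronectin FN1 by 1.39 (SE 0.19) and the growth factor carrier IGFBP4 by 2.32 (SE 0.32). Lysosomal proteins had a median of 0.67 and 27 of 41 members higher against 1 lower, or 29 and 1 adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). Progranulin GRN rose by 1.84 (SE 0.23) and the protease CTSD by 1.34 (SE 0.22). Genes of the oligosaccharyltransferase and N-glycan synthesis had a median of 0.61, with 17 of 30 higher and 1 lower, or 21 and 1 adjusted over the list alone (adjusted p = 0.510 with an estimated correlation). DAD1, a subunit of that enzyme, rose by 0.99 (SE 0.18).

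Further ER-targeted lists were higher with TMM scaling, with medians that fell below 0 under library size alone. ER targeting and translocation genes, a list that holds both reporter genes, had 16 of 34 members higher (median 0.58), cell-surface receptors 32 of 61 (median 0.54) and ER chaperones 17 of 36 (median 0.52), with 0 lower in each. Adjusted over the list alone the higher members numbered 22, 38 and 19. With an estimated correlation the adjusted p was 0.437, 0.437 and 0.510. The ER membrane complex subunit EMC7 rose by 1.25 (SE 0.19), the kinesin receptor KTN1 by 1.62 (SE 0.29), the lipoprotein receptor LRP1 by 1.29 (SE 0.21) and the chaperone HYOU1 by 1.20 (SE 0.20). The calls of HYOU1 and DAD1 were lost under library size alone, with log2 values of 0.61 and 0.37. Golgi glycosyltransferases had 18 of 55 members higher and 1 lower (median 0.45), solute carriers 72 of 223 and 7 (median 0.35) and TMEM genes 49 of 208 and 2 (median 0.29). Adjusted over the list alone these were 26 and 3, 76 and 8, and 60 and 3, and the adjusted p was 0.510, 0.437 and 0.510 with an estimated correlation. The galactosyltransferase B4GALT1 rose by 1.15 (SE 0.19), the fatty acid transporter SLC27A6 by 2.77 (SE 0.29) and TMEM129 by 1.32 (SE 0.18).

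Lists of stress response targets and of cholesterol synthesis, which are not confined to ER proteins, were called as well, again with medians below 0 under library size alone. Targets of the unfolded protein and integrated stress responses had 7 of 26 members higher (median 0.39, 14 higher and 2 lower adjusted over the list alone), with an adjusted p of 0.510 with an estimated correlation and 0.144 under library size alone. SEL1L, of ER-associated degradation, rose by 0.93 (SE 0.17), a call lost under library size alone at a log2 value of 0.31. Cholesterol synthesis had 5 of 25 higher (median 0.30, 11 adjusted over the list alone), among them the demethylase CYP51A1 at 1.31 (SE 0.23). That list's adjusted p was 0.531 with an estimated correlation, 0.242 without LRRC59-BioID replicate 2 and 0.0537 without EV replicate 3. It was also 0.0962 under library size alone and 0.0884 with mitochondrial and non-coding genes left out. Tail-anchored proteins, which enter membranes of the ER or of other compartments after synthesis, did not pass (median 0.11, 3 of 46 members higher and 2 adjusted over the list alone, camera adjusted p = 0.136).

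ZNF genes, which code for nuclear zinc finger proteins, had a median log2 fold change of −0.56. Of 457 tested members 194 were lower and 5 higher, or 249 and 10 adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). ZNF121 fell from 613 ± 166 to 143 ± 17.3 CPM (log2 fold change −2.10, SE 0.28, edgeR adjusted p = 0.000116), and ZNF441, ZNF559, ZNF561 and ZNF562 fell by 2.28, 2.16, 1.80 and 1.80 on the log2 scale. PABPC4L, a poly(A)-binding protein, fell most of the named genes, by 3.72 (SE 0.34, edgeR adjusted p = 8.82e-06), and CENPE, a mitotic kinesin, fell by 1.69 (SE 0.35). Immediate early genes had 5 of 19 members lower (median −0.44, 7 adjusted over the list alone), with an adjusted p of 0.531 with an estimated correlation and 0.167 without LRRC59-BioID replicate 2. Nucleus-retained RNAs had 3 of 16 lower (median −0.56, 4 adjusted over the list alone), among them OIP5-AS1 at −1.27 (SE 0.18). Their adjusted p was 0.531 with an estimated correlation, 0.201 without LRRC59-BioID replicate 2 and 0.113 without EV replicate 1.

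Histone genes had a median of 0.76, with 29 of 58 members higher and 0 lower, or 37 and 2 adjusted over the list alone (adjusted p = 0.531 with an estimated correlation). HIST1H2AE rose by 1.42 (SE 0.26), though histone copies share sequence and reads. Mitochondrially encoded mRNAs had a median of 0.98 and 5 of 13 members higher, or 10 adjusted over the list alone (adjusted p = 0.510 with an estimated correlation), with MT-ND5 of respiratory complex I at 1.38 (SE 0.25). Under library size alone the median was 0.33, and these mRNAs together took 0.594 ± 0.0428% of gene counts against 0.492 ± 0.218% in EV (two-sided exact permutation p = 0.5), where EV replicate 1 had 0.740%, above each LRRC59-BioID library. The total of these shares includes 7SL, at 31.7% in LRRC59-BioID and 0.344% in EV. Nuclear genes of the respiratory chain had 20 of 78 higher and 1 lower (median 0.37, 26 and 3 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation), with a median below 0 under library size alone.

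Lists of glycolysis, cytoskeleton, proteasome, ribosomal proteins and biotin carboxylases were called higher too, and their medians fell below 0 under library size alone. Glycolysis had 2 of 17 members higher (median 0.52, 2 adjusted over the list alone), cytoskeleton 5 of 41 (median 0.32, 4 adjusted over the list alone) and the proteasome 7 of 35 (median 0.32, 7 adjusted over the list alone). For each the adjusted p was 0.531 with an estimated correlation, and without LRRC59-BioID replicate 2 it was 0.108, 0.0977 and 0.0668. PSMB6, a catalytic proteasome subunit, rose by 1.38 (SE 0.18). Cytosolic ribosomal proteins had 5 of 85 higher and 1 lower (median 0.19, 2 and 1 adjusted over the list alone), with an adjusted p of 0.793 with an estimated correlation, 0.835 without LRRC59-BioID replicate 1 (median −0.0064) and 0.694 without EV replicate 2. Its call was also lost under library size alone (0.137), with the filter at 1 CPM (0.0642), without mitochondrial and non-coding genes (0.201) and with GC and length offsets (0.467, or 0.260 with the block). Mitochondrial ribosomal proteins had 10 of 77 higher and 5 lower (median 0.27, 10 and 5 adjusted over the list alone, adjusted p = 0.681 with an estimated correlation). The carboxylase list, which holds genes of biotin handling beside genes of carboxylases, had 2 of 10 higher (median 0.48, 4 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation). Both lists lost their call with the replicate block (adjusted p = 0.0592 for each). Without LRRC59-BioID replicate 2 their adjusted p was 0.0812 and 0.272. The ribosomal list stood at 0.193, 0.0756 and 0.146 without LRRC59-BioID replicate 1, EV replicate 2 or EV replicate 3, and the carboxylases at 0.0848 without EV replicate 1. In the same order of settings as for cytosolic ribosomal proteins, the mitochondrial ribosomal list stood at 0.562, 0.0573, 0.205, 0.366 and 0.417. The carboxylases stood at 0.0677 under library size alone, 0.0813 without mitochondrial and non-coding genes and 0.0623 with the offsets and block.

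Lists that did not pass in LRRC59-BioID were translation factors (median 0.24, 5 of 35 higher and 1 lower), cytosolic chaperones (0.23, 6 of 30 and 1), splicing factors (−0.07, 1 of 45 and 3), hosts of small nucleolar RNAs (−0.13, 0 of 15 and 1), cell cycle genes (0.09, 4 of 35 and 1) and markers of other cell types (0.09, 1 of 7 and 2). Adjusted over the list alone, 5, 7, 0, 0, 3 and 1 were higher and 1, 1, 1, 0, 1 and 2 lower. The camera adjusted p was 0.0669, 0.0807, 0.303, 0.365, 0.591 and 0.591. Translation factors passed without LRRC59-BioID replicate 3 (adjusted p = 0.0404), without EV replicate 1 (0.0216), in a fit of the 6 compared libraries (0.0493) and with GC and length offsets (0.0453, or 0.0399 with the block). Cytosolic chaperones passed without LRRC59-BioID replicate 1 or 3 (0.0254 and 0.0156), and hosts of small nucleolar RNAs without LRRC59-BioID replicate 1 (0.0405, median −0.40). With an estimated correlation on all libraries, the adjusted p was 0.676 for translation factors, 0.676 for cytosolic chaperones and 0.793 for these hosts. The small heat shock protein HSPB1 rose by 1.97 (SE 0.25) and the synaptic vesicle protein SYT1 by 2.65 (SE 0.58).

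Adding the replicate number as a block gave 2876 higher and 2249 lower genes in place of 1940 and 1293. Library size alone gave 336 higher and 8504 lower genes, so that 3.80% of calls were higher instead of 60.0%. With offsets for GC content and length, added after the data were seen, plus the block, 49.1% were higher. Lower genes numbered 853, 494 and 693 without LRRC59-BioID replicate 1, 2 or 3 and 279 without EV replicate 2, higher genes 1244 without LRRC59-BioID replicate 2 and 805 without EV replicate 2, and lists called 15 without LRRC59-BioID replicate 2.

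**Figure D3:**
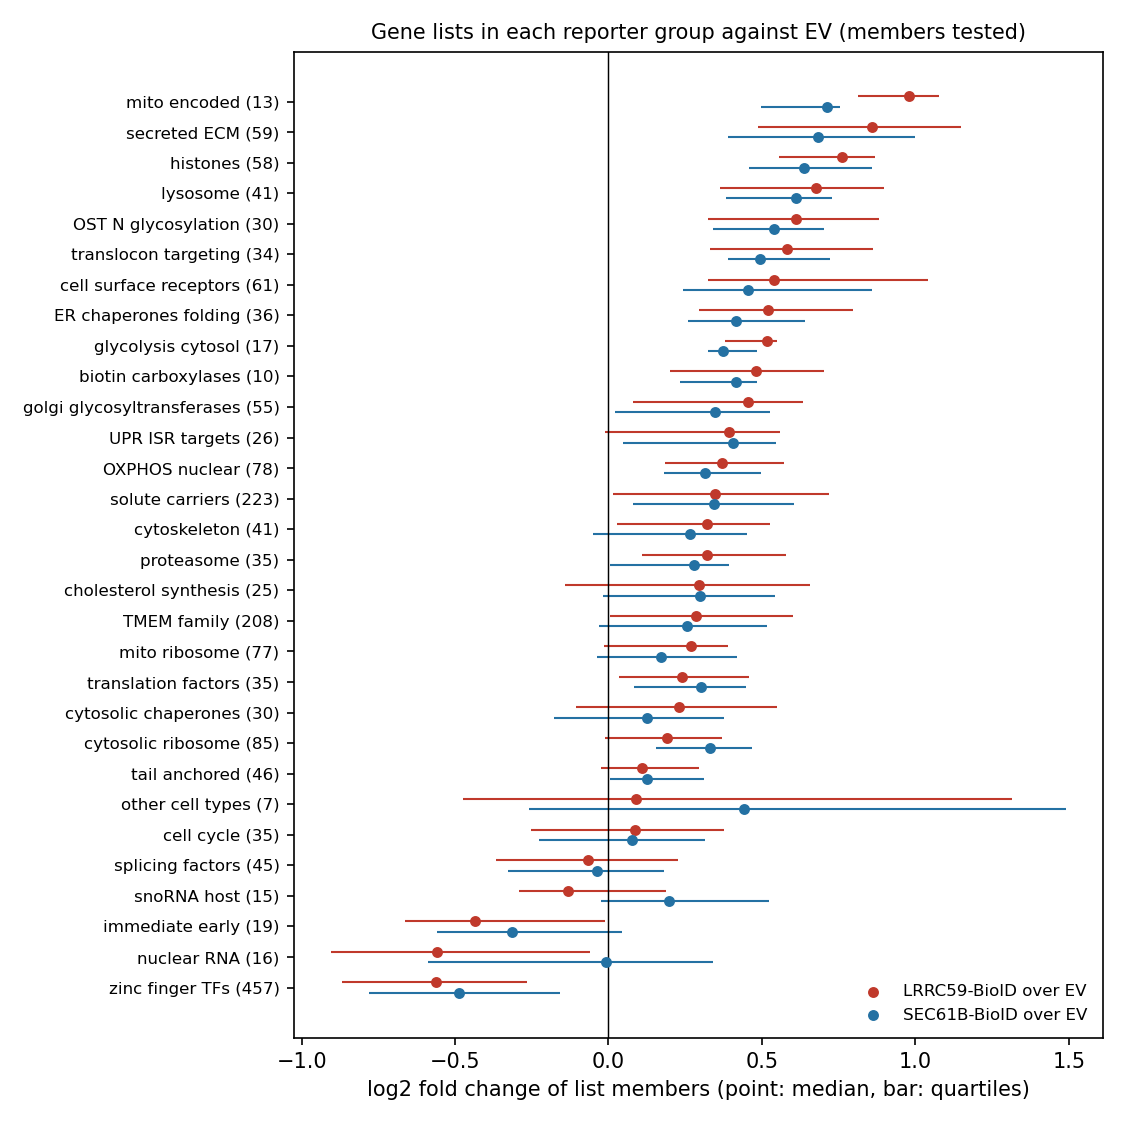
Median (points) and quartiles (bars) of the log2 fold change over EV of the tested members of 30 gene lists, with the number of members in brackets, for LRRC59-BioID (red) and SEC61B-BioID (blue) after TMM scaling. Secreted proteins lie at 0.86 and 0.68 and ZNF genes at −0.56 and −0.49, while under library size alone the medians of 15 lists called against EV in LRRC59-BioID and of 7 in SEC61B-BioID change sign. Relative to the median of all tested genes, 0 of these lists change sign.

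The same question was asked of SEC61B-BioID against EV, for mRNAs on polysomes near the SEC61 channel. Here too a difference in expression between the lines cannot be told apart from recovery. Again messages for secreted, lysosomal, cell-surface and ER proteins were higher and ZNF messages lower. None of these list calls passed with an estimated correlation (lowest adjusted p = 0.497). edgeR called 1405 genes higher and 955 lower, 431 and 360 of them by at least 2-fold. Group values did not overlap for 31.7% of tested genes, against 10% by chance. BMP2, a secreted growth factor (chromosome 20, 6767664 to 6780280), had the largest rise among called protein-coding genes with at least 20 CPM in the higher group and no overlap of libraries, from 2.19 ± 0.365 to 27.0 ± 4.27 CPM (log2 fold change 3.62, SE 0.22, edgeR adjusted p = 1.04e-07). AIMP1, VCL, MARS and QARS rose by 2.86 (SE 0.47), 2.85 (SE 0.50), 2.40 (SE 0.45) and 2.07 (SE 0.39), with edgeR adjusted p of 0.00418, 0.00450, 0.00435 and 0.00413. EPRS, at 1.30 (SE 0.43), did not pass (edgeR adjusted p = 0.0638). ASTN1 rose by 2.60 (SE 0.19), HTRA1 by 2.24 (SE 0.25), the membrane protein PLPPR3 by 1.99 (SE 0.24) and the secreted SERPINF1 by 1.91 (SE 0.20).

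Camera called 22 lists in SEC61B-BioID, 20 higher and 2 lower, of which 0 passed with an estimated correlation (lowest adjusted p = 0.497), and fry called 13. Those 13 were the ER-targeted lists, stress response targets, tail-anchored proteins, ZNF genes and markers of other cell types (fry adjusted p from 0.0236 to 0.0376). Of the 10 splits of the 6 libraries, camera called as many lists or more in 3, the real split included. Secreted and matrix proteins had 34 of 59 members higher and 0 lower (median 0.68), lysosomal proteins 21 of 41 and 0 (median 0.61), receptors 24 of 61 and 1 (median 0.46) and ER targeting genes 8 of 34 and 0 (median 0.49). Adjusted over the list alone these were 41 and 0, 30 and 2, 32 and 1, and 20 and 0, and each had an adjusted p of 0.497 with an estimated correlation. LAMA1 rose by 1.37 (SE 0.21), GRN by 1.56 (SE 0.23), NOTCH3 by 1.75 (SE 0.22), the adhesion protein L1CAM by 1.58 (SE 0.26) and EMC7 by 0.96 (SE 0.18). N-glycosylation genes had 11 of 30 higher (median 0.54) and ER chaperones 13 of 36 (median 0.42), 0 lower in both, or 18 and 16 higher and 1 and 0 lower adjusted over the list alone (adjusted p = 0.566 and 0.597 with an estimated correlation). Golgi glycosyltransferases had 10 of 55 higher (median 0.35), solute carriers 50 of 223 (median 0.34) and TMEM genes 31 of 208 (median 0.26, below 0 under library size alone), with 1, 3 and 2 lower. Adjusted over the list alone, 14, 69 and 40 were higher and 2, 6 and 4 lower (adjusted p = 0.597, 0.497 and 0.597 with an estimated correlation). Stress response targets had 7 of 26 higher (median 0.41, 13 higher and 1 lower adjusted over the list alone, adjusted p = 0.559 with an estimated correlation).

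ZNF genes had 130 of 457 members lower and 8 higher in SEC61B-BioID (median −0.49), or 206 and 10 adjusted over the list alone (adjusted p = 0.497 with an estimated correlation). ZNF121 stood at 170 ± 58.1 CPM against 613 ± 166 in EV (log2 fold change −1.85, SE 0.27, edgeR adjusted p = 0.000677), ZNF441 fell by 2.16 on the log2 scale and PABPC4L by 2.16. Histone genes had 19 of 58 higher and 1 lower (median 0.64), or 32 and 1 adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). Mitochondrially encoded mRNAs had a median of 0.71 with MT-ND5 alone called, by 1.06 (SE 0.24), 1 member also adjusted over the list alone (adjusted p = 0.597 with an estimated correlation, 0.0521 for the list without EV replicate 3). MT-ND5 lost its call without EV replicate 2 (log2 fold change 1.06, edgeR adjusted p = 0.0502). Under library size alone the median was 0.39, and the share of gene counts was 0.677 ± 0.0778% (two-sided exact permutation p = 0.3 against EV). By replicate number that share was 0.763%, 0.657% and 0.612% in SEC61B-BioID against 0.740%, 0.402% and 0.333% in EV. Nucleus-retained RNAs had a median of −0.01 and did not pass (1 of 16 higher, 0 adjusted over the list alone, camera adjusted p = 0.600).

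Further lists were called higher in SEC61B-BioID, with few of their members called. Nuclear genes of the respiratory chain had 10 of 78 higher (median 0.31, 10 adjusted over the list alone, adjusted p = 0.619 with an estimated correlation), glycolysis 1 of 17 (0.37, 3, 0.614) and the carboxylases 1 of 10 (0.42, 1, 0.614), in the same order of values. Tail-anchored proteins had 3 of 46 (0.13, 3, 0.597), and these 3 include the reporter gene SEC61B itself (log2 fold change 3.32). Cytosolic ribosomal proteins had 4 of 85 with 1 lower (0.33, 1 and 1, 0.707), translation factors 3 of 35 (0.30, 0, 0.634), cytoskeleton 3 of 41 (0.26, 1, 0.634) and the proteasome 6 of 35 with 1 lower (0.28, 6 and 2, 0.634). The medians of these last 5 lists and of the respiratory chain fell below 0 under library size alone. Immediate early genes had 2 of 19 lower (median −0.31, 2 adjusted over the list alone, adjusted p = 0.619 with an estimated correlation). These calls were lost in several settings. Without SEC61B-BioID replicate 3 the adjusted p was 0.0550 for glycolysis, 0.0889 for the carboxylases, 0.0864 for translation factors and for immediate early genes, 0.337 for cytoskeleton and 0.137 for the proteasome. Without SEC61B-BioID replicate 1 it was 0.0673 for tail-anchored and 0.330 for ribosomal proteins. Without EV replicate 2 it was 0.112 for ribosomal proteins and 0.121 for translation factors, without EV replicate 1 0.0607 for the carboxylases and 0.0536 for cytoskeleton, and without EV replicate 3 0.0724 for the proteasome. Under library size alone it was 0.160 for tail-anchored proteins, 0.0558 for translation factors, 0.0721 for cytoskeleton, 0.103 for the proteasome and 0.0511 for the carboxylases. With mitochondrial and non-coding genes left out the same 5 lists stood at 0.168, 0.108, 0.139, 0.108 and 0.0684. Cytoskeleton stood at 0.0522 with the filter at 1 CPM and at 0.110 with GC and length offsets, and with the block added to the offsets cytoskeleton stood at 0.124 and the proteasome at 0.0683.

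Lists that did not pass in SEC61B-BioID were cholesterol synthesis (median 0.30, 3 of 25 higher and 1 lower), cytosolic chaperones (0.12, 1 of 30 and 1), splicing factors (−0.04, 0 of 45 and 0), mitochondrial ribosomal proteins (0.17, 4 of 77 and 3), hosts of small nucleolar RNAs (0.20, 1 of 15 and 0), cell cycle genes (0.08, 2 of 35 and 1) and markers of other cell types (0.44, 2 of 7 and 1). Adjusted over the list alone, 5, 1, 0, 2, 1, 1 and 2 were higher and 1, 1, 0, 2, 0, 1 and 2 lower. The camera adjusted p was 0.0747, 0.346, 0.325, 0.0747, 0.0860, 0.749 and 0.0860, and with the replicate block the hosts of small nucleolar RNAs passed (adjusted p = 0.0407, but adjusted p = 0.495 with an estimated correlation). These hosts also passed without SEC61B-BioID replicate 2 or 3 (0.0278 and 0.0466), without EV replicate 1 (0.0172) and with the offsets and block (0.0449). Without SEC61B-BioID replicate 2 or EV replicate 1, cholesterol synthesis passed (0.0428 and 0.0268), as did mitochondrial ribosomal proteins (0.00532 and 0.0104, medians 0.27 and 0.27). Markers of other cell types passed under library size alone (0.0220), without EV replicate 2 (0.0443) and with fry (0.0376). With an estimated correlation on all libraries, the adjusted p was 0.634 for cholesterol synthesis, 0.707 for mitochondrial ribosomal proteins and 0.497 for markers of other cell types.

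With the replicate block 2530 genes were higher and 2004 lower, and library size alone gave 381 higher and 3103 lower, so that 10.9% of calls were higher instead of 59.5%. Library size alone moved the median of all tested genes to −0.32. Relative to that median, 0 of the 22 called lists changed sign. The GC and length offsets with the block gave 48.8%. Higher genes numbered 567 and 613 without SEC61B-BioID replicate 1 or 3 and 386 without EV replicate 2, and lower genes 210, 1543 and 172 without SEC61B-BioID replicate 1, 2 or 3 and 582 and 148 without EV replicate 1 or 2.

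Both reporters were then set side by side. Of the genes called against EV, 1207 were higher and 702 lower with both reporters and 0 went opposite ways, where independent lists of these sizes would share 159.5 and 72.3. Across tested genes, which are not independent replicates, the log2 fold changes correlated with r = 0.879 and rho = 0.866, and over all genes with at least 1 read with r = 0.561. In 20 simulations all 9 libraries were drawn from the EV means, and both unchanged reporter groups were set against the same simulated EV libraries. These gave r = 0.467 on average. They gave no shared calls, but each simulated contrast had at most 2 calls, so this is no measure for the shared calls above. The covariance was 0.381 against a simulated 0.0438, a difference of 0.337. The simulated libraries were independent of each other and do not carry the pairing by replicate number, so this difference is not a measured shared part. The 3 EV libraries were not split into separate controls for each reporter, so part of the excess in overlap may come from sharing them.

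**Figure D4:**
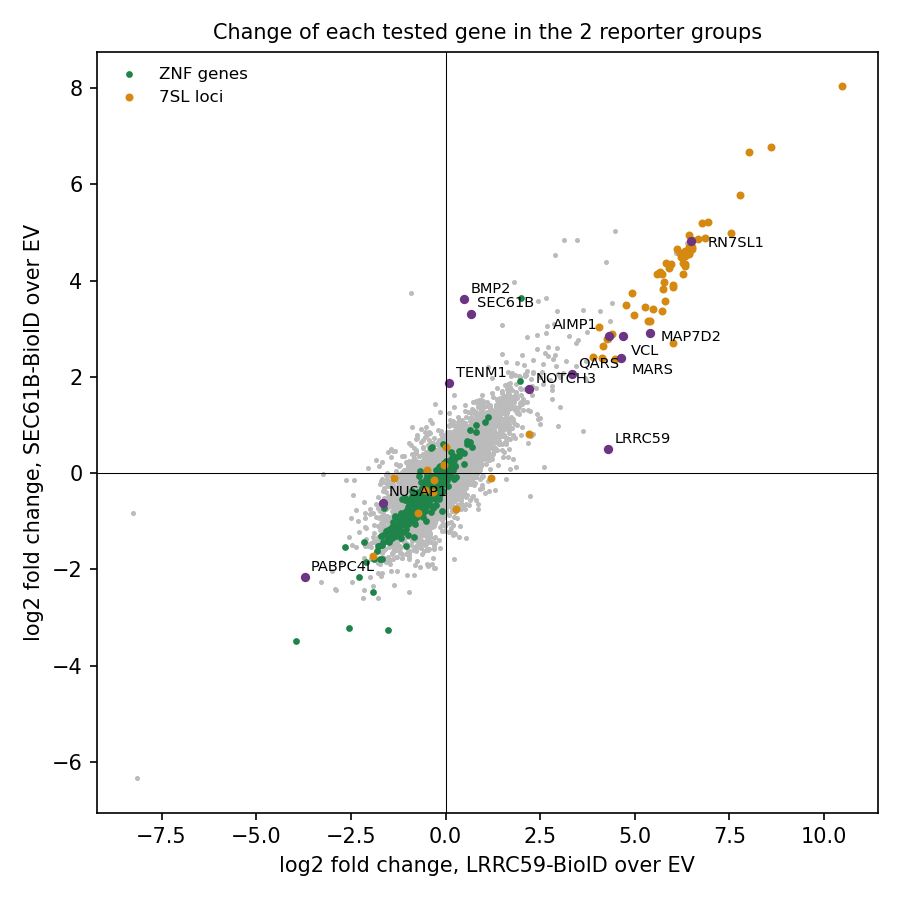
Log2 fold change over EV of each of 17086 tested genes in LRRC59-BioID (x axis) and SEC61B-BioID (y axis) after TMM scaling, with ZNF genes in green, 7SL loci in orange and named genes in purple. LRRC59 and MAP7D2 lie to the right, and BMP2, SEC61B and TENM1 stand above the diagonal band.

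The direct comparison of LRRC59-BioID with SEC61B-BioID asks which mRNAs were recovered more with either reporter. Besides the reporter genes, MAP7D2, NALCN and ULK2 were higher with LRRC59-BioID and BMP2, TENM1 and NUSAP1 with SEC61B-BioID. Of these, ULK2 and NUSAP1 were not called above EV with either reporter. edgeR called 13 genes higher and 4 lower, with 704 at an unadjusted p under 0.05, and groups did not overlap for 9.25% of genes, near the 10% of chance. LRRC59 differed by 3.80 (SE 0.27, edgeR adjusted p = 7.04e-07) and SEC61B by −2.65 (SE 0.27, edgeR adjusted p = 0.000111). MAP7D2 stood at 25.3 ± 3.88 against 4.50 ± 0.362 CPM (log2 fold change 2.49, SE 0.20) and NALCN, a sodium leak channel, at 22.1 ± 2.54 against 6.55 ± 1.30 CPM (1.75, SE 0.22). BMP2 stood at 3.11 ± 0.313 against 27.0 ± 4.27 CPM (−3.12, SE 0.22) and TENM1, a teneurin adhesion protein, at 5.95 ± 0.632 against 20.3 ± 0.246 CPM (−1.77, SE 0.19). In EV the same 4 genes stood at 0.585, 6.04, 2.19 and 5.50 CPM. The autophagy kinase ULK2 differed by 1.15 (SE 0.20, edgeR adjusted p = 0.0261) and NUSAP1, a spindle protein, by −1.05 (SE 0.18, edgeR adjusted p = 0.0250), where EV stood at 20.1 and 175 CPM. ULK2 stood at 23.7 CPM in LRRC59-BioID and 10.7 CPM in SEC61B-BioID, and was called against EV only as lower in SEC61B-BioID (edgeR adjusted p = 0.00748). NUSAP1 stood at 55.3 and 114 CPM and was called lower than EV in both (edgeR adjusted p = 1.90e-05 and 0.0287). MARS, at 2.24, did not pass (edgeR adjusted p = 0.0711).

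Of the lists, camera called 9, with 5 higher and 4 lower in LRRC59-BioID, each with an adjusted p of 0.916 with an estimated correlation. All 10 splits of the 6 libraries into 3 and 3, the real one included, called as many lists or more, up to 24. These calls therefore do not set the reporters apart. Host transcripts of small nucleolar RNAs had the lowest p, with a median of −0.31 and 0 of 15 members called, 2 of them lower adjusted over the list alone. The medians of secreted proteins and ZNF genes were 0.13 and −0.10 with 0 members called in each, also adjusted over the list alone, and that of secreted proteins was −0.17 under library size alone, which moved the median of all tested genes to −0.31. The lists called numbered 4 and 20 without LRRC59-BioID replicate 2 or 3 and 17 and 14 without SEC61B-BioID replicate 1 or 3. DESeq2 called 75 genes higher and 16 lower, library size alone 7 and 15, and 59, 6, 6 and 5 genes were higher without LRRC59-BioID replicate 2 or 3 or SEC61B-BioID replicate 1 or 2. Leaving out any SEC61B-BioID replicate, or LRRC59-BioID replicate 1 or 3, ended the call of NUSAP1 or ULK2, with edgeR adjusted p up to 0.154, and library size alone ended that of ULK2 (0.84, edgeR adjusted p = 0.144).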

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

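The tests of the 3 patterns below were chosen after the results were seen, and the splits of the libraries and the direct comparison of the reporters were planned.

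The effects of the reporters against EV differed from each other for 8 named genes, by the edgeR test of LRRC59-BioID against SEC61B-BioID. The log2 differences were 3.80 for LRRC59, 2.49 for MAP7D2, 1.75 for NALCN, 1.15 for ULK2, −1.05 for NUSAP1, −1.77 for TENM1, −2.65 for SEC61B and −3.12 for BMP2. Against EV, BMP2 and TENM1 were called only in SEC61B-BioID (3.62 and 1.88, against 0.50 and 0.10 in LRRC59-BioID) and NALCN only in LRRC59-BioID (1.87 against 0.12). ULK2 was called only as lower in SEC61B-BioID (−0.91, against 0.24 in LRRC59-BioID). NUSAP1 was called lower in both (−1.66 in LRRC59-BioID and −0.61 in SEC61B-BioID). Between the reporters, the calls of ULK2 and NUSAP1 were each lost without at least 1 library. Without LRRC59-BioID replicate 3 their edgeR adjusted p was 0.150 and 0.154, without LRRC59-BioID replicate 1 it was 0.108 and 0.106, and without SEC61B-BioID replicate 3 it was 0.110 for both. Without SEC61B-BioID replicate 2 it was 0.149 and 0.0505, and NUSAP1 stood at 0.0947 without SEC61B-BioID replicate 1. The lines also differ in doxycycline dose and were made separately, so neither can be separated from the reporter.

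By camera with the preset correlation, 9 lists were called between the reporters. All 10 splits of these libraries, the real one included, called as many or more, so the count does not set the real grouping apart. Medians were higher in LRRC59-BioID for ER targeting (0.0956), ER chaperones (0.129), secreted proteins (0.131), receptors (0.0953) and mitochondrially encoded mRNAs (0.302), and each of these 5 medians was below 0 under library size alone. Medians were lower for ZNF genes (−0.0964), nucleus-retained RNAs (−0.237), hosts of small nucleolar RNAs (−0.310) and 7 markers of other cell types (−0.354). With an estimated correlation the adjusted p was 0.916 for each. Without LRRC59-BioID replicate 2 the calls of 7 lists were lost, and the medians of ER targeting, ER chaperones and receptors changed sign (−0.0139, −0.0046 and −0.0042). Without SEC61B-BioID replicate 2 the calls of 6 lists were lost, and ZNF genes changed sign (0.0579). Mitochondrially encoded mRNAs also lost the call without LRRC59-BioID replicate 1 (adjusted p = 0.514) and ER targeting and ER chaperones without SEC61B-BioID replicate 3 (0.0987 and 0.169). Markers of other cell types lost it without LRRC59-BioID replicate 1 or 3 (0.0609 and 0.0689) or SEC61B-BioID replicate 1 (0.191). Under library size alone the calls of ER targeting (0.205), ER chaperones (0.286), receptors (0.215) and markers of other cell types (0.215) were lost. With GC and length offsets and the block, those of ER targeting (0.0591), mitochondrially encoded mRNAs (0.0831) and markers of other cell types (0.111) were lost.

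In the counter lines, which the gene tests do not use, the share of reads with more than 1 alignment was 74.9% in LRRC59-BioID and 63.6% in SEC61B-BioID, against 48.0% in EV. The share of ambiguous reads was 4.24% and 3.70%, against 2.24%.

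The first pattern is that ZNF mRNAs were lower in both reporter groups than in EV (medians −0.56 and −0.49). The data argue against GC content and transcript length as the whole cause. With offsets for both and the replicate block the medians were −0.52 and −0.45 (nearer value −0.446), against −0.56 and −0.49 with the block alone. The median of all tested genes was −0.0700 and −0.0385 with the offsets and block, against −0.0210 and 0.0105 with the block alone. Relative to all genes, the offsets therefore reduced the fall by more than the ZNF medians alone show. They also argue against dilution of every mRNA not targeted to the ER, since 6 lists of cytosolic and splicing proteins had a median of at least 0.217 with TMM scaling, where dilution would bring them as low as the ZNF genes. Nuclear RNA carried over in EV stays open, as nucleus-retained RNAs had medians of −0.56 and −0.0092 with members on both sides. A lower share of ZNF mRNAs on labelled ER polysomes stays open beside it, as does a difference between the lines.

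The second pattern is that 7SL RNA was higher in both reporter groups. A move of assigned reads between its copies cannot create it, since the sum over all loci was still at least 42.6 times that of EV. Reads with more than 1 alignment are left unassigned and are not in this sum. A difference between groups in the part of 7SL reads that was assigned therefore stays open. RMRP, RN7SK, RPPH1 and SCARNA2 did not rise as 7SL did. Their medians were 0.248 in LRRC59-BioID and 0.716 in SEC61B-BioID. Their log2 change plus 2 standard errors reached at most 1.69, while RN7SL1 changed by 6.48 and 4.83. This argues against an equal retention of these 4 RNAs only, which all belong to the list of nucleus-retained RNAs. Other short structured RNAs were not tested, so their retention stays open. Also open, as a hypothesis not tested here, is that labelled polysomes carry signal recognition particle, beside a difference between the lines themselves.

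The third pattern is that MARS, AIMP1, QARS, EPRS and VCL stood above EV. A single library is argued against, since without LRRC59-BioID replicate 2 the number still called at a log2 fold change of at least 1 in LRRC59-BioID was 5 of these 5 genes. GC content and transcript length are argued against as the whole cause, since with those offsets and the replicate block 5 of 5 were called in each reporter group, although EPRS lacked a call in SEC61B-BioID without them (edgeR adjusted p = 0.0638) and in LRRC59-BioID without EV replicate 2 (0.0518). A rise of every mRNA of the complex by as much is argued against by its 7 other members, with medians of 0.371 and 0.253. With the offsets and block, KARS, RARS, DARS and AIMP2 were called higher in LRRC59-BioID (0.46, 0.53, 0.47 and 0.51). IARS and AIMP2 were called in SEC61B-BioID (0.52 and 0.50), and the rest of the 7 were not called in that fit, so some members rose by less. Recovery of the mRNAs of the first 5 genes through labelled proteins and a difference between the lines both stay open, and neither was tested.

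With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For the counts of genes, 1 split gave as many as the real one, itself, in each comparison and direction. The real counts were 1940 and 1293 for LRRC59-BioID against EV, 1405 and 955 for SEC61B-BioID against EV, and 13 and 4 between the reporters, and the highest count of any other split was 0, including splits that part 3 same-numbered pairs. For the counts of lists, 4, 3 and 10 splits gave as many. The real counts were 23, 22 and 9, and the highest of the others 25, 24 and 24.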

How the results depend on the processing

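GC and length offsets were chosen after the results were seen, and all other alternatives were planned.

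The direction and call of LRRC59 in LRRC59-BioID and of SEC61B in SEC61B-BioID held under each alternative run, with log2 fold changes of 4.10 to 4.41 and 2.99 to 3.59 when 1 library was left out. The main counts were 1940 higher and 1293 lower genes for LRRC59-BioID, 1405 and 955 for SEC61B-BioID, and 13 and 4 between the reporters.

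Library size alone gave 336 and 8504, 381 and 3103, and 7 and 15. A minimum of 2-fold gave 620 and 434, and 431 and 360. Testing every gene with at least 1 read gave 102 and 25 genes between the reporters and a correlation of both reporters' changes of 0.561 in place of 0.879. DESeq2 gave 75 and 16 between the reporters. The replicate block gave 2876 higher and 2249 lower genes in LRRC59-BioID, 2530 and 2004 in SEC61B-BioID and 79 and 20 between the reporters, where deviations of same-numbered libraries did not pair (0.368, 0.0799 and −0.0347). Between the reporters the block ended the call of markers of other cell types (adjusted p = 0.0850) and gave one to cytosolic ribosomal proteins (0.0277, but 0.928 with an estimated correlation). The offsets gave 1982 lower genes of 4084 called in LRRC59-BioID, 1521 lower of 3114 called in SEC61B-BioID, and 53 higher and 18 lower between the reporters. With the block they gave 2782 lower genes of 5466 called in LRRC59-BioID, 2271 higher and 2380 lower in SEC61B-BioID, and 84 and 27 between the reporters. The 2-fold minimum lowers counts by its construction. Library size alone drops the TMM factors, which shifts the genes of a comparison together and moves its counts towards lower genes. The median of all tested genes then stood at −0.65 in LRRC59-BioID, −0.32 in SEC61B-BioID and −0.31 between the reporters. Relative to that median, 0 of the called lists changed sign in each comparison. For the remaining settings the cause was not tested. Lists called were 23, 22 and 9 with the preset correlation, 0, 0 and 0 with an estimated one, and 11, 13 and 0 with fry.

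With 1 library left out, 805 to 1922 genes were higher and 279 to 1516 lower in LRRC59-BioID, 386 to 1810 and 148 to 1543 in SEC61B-BioID, and 5 to 59 and 3 to 5 between the reporters. Lists numbered 15 to 25, 17 to 25 and 4 to 20, and the correlation ran from 0.824 to 0.886. Counts that fell have fewer libraries as part of their cause, and the cause of counts that rose was not tested.

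Changes of direction were seen for 4 named genes and, by camera's direction relative to other genes, for 6 lists called in at least 1 of the settings compared. With library size alone, STX18 stood at −0.0164, RHOT1 at −0.10, ARPC4 at −0.0291 and AHSA1 at −0.00016 in LRRC59-BioID. Between the reporters and with 1 library left out, medians ran from −0.0046 to 0.234 for ER chaperones, −0.0042 to 0.176 for receptors and −0.148 to 0.0827 for cell cycle genes, each lowest without LRRC59-BioID replicate 2. They ran from −0.257 to 0.116 for ribosomal proteins, highest without SEC61B-BioID replicate 1, and from −0.173 to 0.0579 for ZNF genes and −0.110 to 0.181 for histones, which changed sign without SEC61B-BioID replicate 2. Of the values of named genes under alternatives, 3391 kept direction and side of the threshold and 417 lost the call, 98 of these with library size alone and 91 without EV replicate 2. Of those of lists, 1192 kept both, 173 lost the call and 60 gained it. Medians that crossed 0 without a change of camera's direction are not among the 6, as many did with library size alone. With 1 library left out these include ER targeting between the reporters (−0.0139 without LRRC59-BioID replicate 2), cytosolic ribosomal proteins in LRRC59-BioID against EV (−0.0064 without LRRC59-BioID replicate 1) and lists that were not called.

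What limits calls was not tested by varying depth. In simulated counts with the depth, spread and number of these libraries, 21 to 29 of 50 genes changed 2-fold were recovered, against 47 or 48 changed 4-fold.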

Other observations

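All tests in this part were chosen after the results were seen.

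Of 11 synthetases outside the multisynthetase complex, 3 were called higher in LRRC59-BioID and 2 in SEC61B-BioID, with medians of 0.248 in both. They were CARS at 1.08 (SE 0.19), GARS at 0.67 (SE 0.18) and WARS at 0.62 (SE 0.18) in LRRC59-BioID, and GARS at 0.61 (SE 0.18) and WARS at 0.58 (SE 0.18) in SEC61B-BioID. With GC and length offsets and the block, CARS was called in SEC61B-BioID as well (edgeR adjusted p = 0.0323). In that fit FARSB was called in LRRC59-BioID and SEC61B-BioID (edgeR adjusted p = 0.0337 and 0.0239). Without LRRC59-BioID replicate 2, GARS and WARS lost the call in LRRC59-BioID (edgeR adjusted p = 0.0917 and 0.0945). Within the complex AIMP2 was called in both reporter groups (0.72, SE 0.17, and 0.67, SE 0.16), and EEF1E1 had the lowest values (−0.23 and −0.10, neither called).

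Of other abundant RNAs, MALAT1 took 1.60 ± 0.461% of gene counts in LRRC59-BioID, 2.38 ± 0.341% in SEC61B-BioID and 3.04 ± 0.895% in EV. Cytosolic ribosomal protein mRNAs took 3.98 ± 0.389%, 5.41 ± 1.39% and 5.36 ± 1.09%, and ZNF mRNAs 1.38 ± 0.126%, 1.80 ± 0.428% and 3.23 ± 0.487%. Metazoa_SRP took 19.6 ± 4.73%, 9.78 ± 1.93% and 0.121 ± 0.0390%.

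The log2 fold change correlated weakly with GC content across 14758 genes (Spearman rho 0.192 in LRRC59-BioID, 0.245 in SEC61B-BioID and −0.0699 between the reporters). The median GC content was 43.3% for ZNF transcripts and 49.2% for protein-coding ones.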
